A study of Mus musculus with 6 samples.

How the data were processed

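RNA was measured in 6 libraries, 3 of WT haploid and 3 of p53-deficient haploid mouse embryonic stem cells. Sample titles call the second group P53ki, while the genotype field gives it as p53-deficient and the series design as a knockout against WT in triplicate. The report calls it p53-deficient. Per the labels' protocols, mRNA was purified from total RNA with poly-T beads and libraries were built with the NEBNext Ultra kit, which is not stated to mark the strand. Reads of genes with overlapping exons on opposite strands can therefore not be parted, and 3 of the 195 named genes share at least 20% of their exon length with another expressed gene.

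The deposited values are FPKM, fragments per kilobase of gene length scaled to library size, which the authors made per gene and library. Per the submitters' processing notes the build was mm10 and the tools were HISAT2 2.0.5 and featureCounts 1.5.0-p3, whose roles are not given there. FPKM multiplied by the deposited gene length gave whole multiples of a step in 100% of the values above 0 (tolerance 0.001), so reads per gene could be rebuilt. The library total used as divisor was 99.1% to 101% of the reads in listed genes, and how it was set is not given in the sources used here. How reads with several matches were counted is not given either, which matters for genes with near-identical copies. The table held 54532 genes, and 98.3% of those found in GENCODE mouse release 21 had the same coordinates there. Symbols that a spreadsheet had turned into dates, 27 in all, were restored from the gene identifiers.

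Values were taken as log2(FPKM + 1) for genes of mean FPKM at least 0.5. The groups were compared with limma 3.58.1 in R 4.3.3 (variance trend, moderated statistics, both sides), with Benjamini-Hochberg adjustment over 15144 genes, and a gene was called at an adjusted p under 0.05. With 3 libraries against 3, an exact permutation test of a single gene cannot go below 0.1, so the calls rest on the variance shared across genes. Errors beside means are SD over 3 libraries. Of 801 symbols in 27 gene lists, 799 were matched. The 27 lists, the tests of genes, lists and chromosomes, and the rule for named genes were set before the data were examined, and the closing section names the tests and groups chosen later. The rule took Trp53 and 6 known p53 targets, the 12 largest rises and 12 largest falls among called protein-coding genes of mean FPKM at least 1 with non-overlapping groups and a gene name, the 5 most abundant genes changed at least 2-fold, and for each list up to 4 called members and the most abundant member that did not pass. Other genes were named after their values were seen, among them the Y-linked genes, Xist, Pou5f1, Nanog, Nodal, Myc, Bid, Bcl2l11, Amn, Xpc, Triap1, Eif1a, Rian, Mirg, Col1a1, Lgals1 and the pseudogenes set beside ribosomal protein genes.

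Lists and chromosomes were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the lists or the chromosomes. With the correlation estimated from the data, none of the 8 list calls held, with 6 lists at an unadjusted p under 0.05. Ratios of rebuilt reads carry 95% exact binomial intervals, which cover counting error only. Near-identical copies were sought with BLAST+ 2.17.0 among the longest transcripts of tested genes, at 95% identity or more over at least 50% of the shorter transcript and at least 100 bases, and 1931 genes had one.

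The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, scaling by the median log2 ratio, quantile normalization, no variance trend, array weights, the replicate number as a block, protein-coding genes only, voom weights on rebuilt reads, an estimated correlation, an adjusted p under 0.01 and each library left out in turn. The median log2 ratio used for scaling was taken over genes whose mean log2(FPKM + 1) reached that of 5 FPKM. Removal of genes with near-identical copies was added after the data were seen. The fit was tested on simulated reads with 200 planted changes among 15135 genes. It recovered 40% of 1.25-fold, 86% of 1.5-fold, 86% of 2-fold and 100% of 4-fold changes, and called 10 unchanged genes. Its simulated spread was taken from the present replicates and so holds for their kind of replication alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.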

Results

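Poly(A)-selected RNA was sequenced from haploid mouse embryonic stem cells, which carry a single chromosome set and tend to return to the diploid state in culture and during differentiation. The cells are given as strain 129SV. There were 2 groups of 3 libraries: wild-type (WT) haploid cells and p53-deficient haploid cells. The series asks how blocking apoptosis affects that return to diploidy, and its single RNA comparison sets p53-deficient cells against WT. Reads in listed genes, rebuilt from the values, numbered 17065841, 19440659 and 20331905 in the WT libraries and 21218976, 11536412 and 17568406 in the p53-deficient libraries. The labels do not say that the replicates were separate cultures, so the p-values given here measure the spread between these libraries, which may be technical. Nor do the sample titles tell lines or clones apart within a genotype. A difference between lines, clones or cultures can therefore not be told apart from the loss of p53. Ploidy was not measured in these libraries.

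Trp53, which encodes p53 and lies on chromosome 11 (mm10, 69580359 to 69591873, plus strand; ENSMUSG00000059552), was lower in each p53-deficient library than in each WT library. The WT libraries held 64.5, 69.8 and 69.6 FPKM and the p53-deficient libraries 9.71, 9.71 and 9.98 FPKM. The means were 68.0 ± 3.03 and 9.80 ± 0.155 FPKM (SD, n = 3 per group), a log2 fold change of -2.67 with SE 0.0371 (limma adjusted p = 3.57e-08). Trp53 shares near-identical sequence with its processed pseudogene Trp53-ps, which also fell, from 3.73 ± 0.196 to 0.244 ± 0.113 FPKM. Reads still assigned to Trp53 in the p53-deficient libraries say nothing of whether the remaining transcript encodes a protein.

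The difference between the groups reached most expressed genes. Of 15144 genes tested, 5341 were higher and 4733 lower in p53-deficient cells, 66.5% of the total. Of these, 1472 changed at least 2-fold, 518 upward and 954 downward, and at least 4-fold changes numbered 93 upward and 212 downward. The count at an unadjusted p under 0.05 was 10543. In 71.4% of the tested genes the libraries of one group all lay above those of the other, against 10% by chance. The median log2 fold change of all tested genes was 0.03. After scaling each library by its median log2 ratio, which moved the median of all genes to -0.07, 4034 genes were higher and 5846 lower. Quantile normalization gave 5553 higher and 4516 lower, so the balance between rises and falls rests on the choice of scaling. The count of genes changed at least 2-fold was 2603 with a pseudocount of 0.1 and 2780 with voom weights on rebuilt reads.

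Known targets of p53 were lower as a group. Of 48 measured members of the fixed list, 43 were lower, 2 were higher and 3 did not pass, and the counts were 45 lower and 2 higher when adjusted over the list alone. The median log2 fold change was -1.63. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727; ENSMUSG00000023067), went from 87.6 ± 0.523 to 9.66 ± 0.645 FPKM (log2 fold change -3.06). Ccng1 (cyclin G1) fell from 115 ± 2.16 to 9.95 ± 0.152 FPKM, and Mdm2, which encodes the ubiquitin ligase that degrades p53, fell from 49.8 ± 0.890 to 13.9 ± 0.629 FPKM. Eda2r, a receptor of the tumour necrosis factor family, fell furthest on the log2(FPKM + 1) scale, from 23.5 ± 0.341 to 0.387 ± 0.0610 FPKM (log2 fold change -4.14), followed on that scale by Psrc1 at -3.48 and Phlda3 at -3.46. Xpc and Triap1 were the members that rose, with log2 fold changes of 0.20 and 0.26, although Xpc did not pass after scaling by the median log2 ratio. Tigar had a log2 fold change of -0.06 and did not pass. The camera test on the list gave an adjusted p of 3.94e-15 with the preset correlation, and adjusted p = 0.0891 with an estimated correlation. Reads of 4 Y-linked genes, described with the fibroblast genes, were 9.84 times lower in the same libraries.

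**Figure D1:**
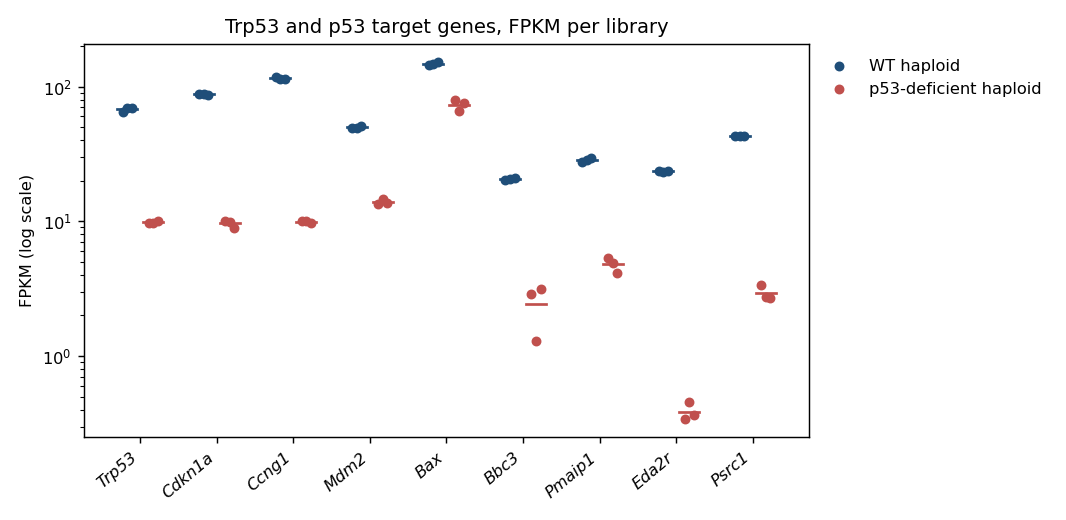
FPKM of Trp53 and 8 p53 target genes in each library (points, log scale), with the mean of each group as a horizontal line. Trp53 lies near 68.0 FPKM in WT and 9.80 FPKM in p53-deficient libraries, and the groups do not overlap for any gene shown.

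Apoptosis genes moved in both directions. In the pro-apoptotic mitochondrial list, 13 of 27 members were lower, 9 higher and 5 did not pass. The BH3-only genes Bbc3 (Puma) and Pmaip1 (Noxa) fell from 20.6 ± 0.429 to 2.43 ± 0.984 FPKM and from 28.5 ± 1.06 to 4.81 ± 0.613 FPKM. Bax, which encodes a pore-forming protein of the mitochondrial outer membrane, fell from 148 ± 3.98 to 73.4 ± 7.12 FPKM (log2 fold change -1.01), and Apaf1, which encodes the core of the apoptosome, fell with a log2 fold change of -1.03. Bnip3 fell with -2.53. Bid and Bcl2l11 (Bim) rose with 0.66 and 0.51, where 17.7% of the exon length of Bid overlaps Bcl2l13, and Bak1 was 29.1 ± 0.329 against 30.5 ± 1.61 FPKM without passing. The list was not called by camera (adjusted p = 0.322). In the death receptor list 10 of 16 members were lower, 3 higher and 3 did not pass, or 11, 1 and 4 after scaling by the median log2 ratio, with Dap at -1.73, Fas at -1.57 and Tnfrsf10b at -1.35, while Tnfrsf25 rose with 1.14. Its camera adjusted p of 0.0399 became adjusted p = 0.202 with an estimated correlation, and the call also ended with each scaling alternative, with protein-coding genes only, without genes that have a near-identical copy and without WT replicate 3, where adjusted p lay between 0.0549 and 0.0680. The Y-linked reads were 9.84 times lower in these libraries as well. Of 16 anti-apoptotic genes, 6 were higher and 6 lower (camera adjusted p = 0.822), or 6 and 7 after scaling by the median log2 ratio. Pim2 rose with 1.22, and Cflar, Tnfaip3 and Birc3 fell with -1.05, -0.93 and -0.86. Cflar shares sequence with an expressed near-identical copy.

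Genes typical of fibroblasts, fixed as markers of feeder cells, fell without exception. All 30 measured members were lower, and 30 were lower when adjusted over the list alone, with a median log2 fold change of -1.83 (camera adjusted p = 2.16e-15, and adjusted p = 0.0891 with an estimated correlation). Lox, which encodes a collagen cross-linking enzyme, fell from 158 ± 1.66 to 14.3 ± 0.318 FPKM. Col3a1 fell from 49.4 ± 0.421 to 6.50 ± 0.105 FPKM, and Thbs1 from 172 ± 2.10 to 25 ± 0.733 FPKM. Lgals1 and Col1a1, the members with the highest WT means, went from 389 to 111 and from 210 to 30.9 FPKM. Genes of the Y chromosome moved with them: Ddx3y went from 1.72 ± 0.243 to 0.176 ± 0.0622 FPKM and Eif2s3y from 1.61 ± 0.0465 to 0.137 ± 0.0337 FPKM. Pooled over Ddx3y, Eif2s3y, Kdm5d and Uty, 1161 reads were counted in WT and 103 in p53-deficient libraries, a depth-adjusted ratio of 9.84 (95% interval 8.04 to 12.2, exact binomial, counting error only). Taken singly the genes differed: Ddx3y had 10.5 (7.68 to 14.7), Eif2s3y 11.2 (7.74 to 16.9), Kdm5d 4.69 (3.02 to 7.59) and Uty 18.8 (8.39 to 52.1). The interval of Kdm5d lay below the pooled one. Xist, the RNA that silences an X chromosome in cells with more than 1, went from 3.48 ± 0.119 to 0.907 ± 0.101 FPKM. The Y-linked genes and Xist were chosen after their values were seen.

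**Figure D2:**
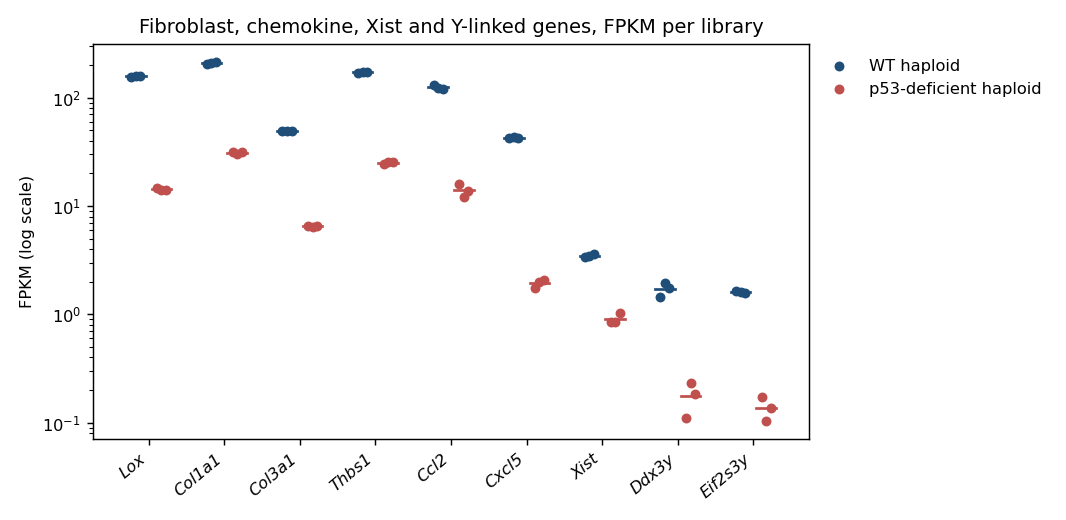
FPKM of fibroblast genes (Lox, Col1a1, Col3a1, Thbs1), chemokine genes (Ccl2, Cxcl5), Xist and the Y-linked genes Ddx3y and Eif2s3y in each library (points, log scale), with group means as lines. Each gene lies lower in the p53-deficient libraries, Lox at 14.3 against 158 FPKM and Ddx3y at 0.176 against 1.72 FPKM.

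Core pluripotency genes stayed abundant in both groups while several of their partners changed. Pou5f1 (Oct4) was 371 FPKM in WT and 407 FPKM in p53-deficient cells, a difference that did not pass after scaling by the median log2 ratio, and Sox2 was 182 ± 2.84 against 173 ± 7.09 FPKM without passing. Nanog fell from 330 to 221 FPKM. Of 31 naive pluripotency genes, 17 were higher, 10 lower and 4 did not pass (camera adjusted p = 0.230, but 0.0393 without a filter on low values). Utf1 rose from 61.6 ± 3.83 to 303 ± 19.4 FPKM, Lin28a from 30.9 ± 0.103 to 89.3 ± 1.96 FPKM, and Gbx2 from 1.80 ± 0.168 to 9.80 ± 0.532 FPKM, although 43.5% of the exon length of Gbx2 overlaps an expressed gene on the opposite strand. Dppa3 (Stella) fell from 51.0 ± 1.49 to 13 ± 0.672 FPKM. Among 20 primed and formative genes, 9 rose and 9 fell (camera adjusted p = 0.903), or 7 and 10 after scaling by the median log2 ratio. Lefty1 and Lefty2, secreted inhibitors and targets of Nodal signalling, fell from 50.8 ± 2.06 to 1.82 ± 0.116 FPKM and from 80.1 ± 1.94 to 4.85 ± 0.580 FPKM. Etv4 and Dusp6, both induced by FGF and ERK signalling, rose from 13.9 ± 0.918 to 66.0 ± 4.12 FPKM and from 6.19 ± 0.300 to 21.3 ± 0.753 FPKM, while Etv5 stood at 110 and 109 FPKM.

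Genes of lineages outside the naive state were mostly low. Of 14 measured primitive endoderm genes, 11 were lower and 2 higher (median log2 fold change -0.90, camera adjusted p = 0.000626, and adjusted p = 0.0891 with an estimated correlation). The type IV collagen genes Col4a2 and Col4a1 fell with -2.61 and -2.34 and Thbd with -1.51, while Amn rose with 1.18. These collagens are also made by fibroblasts, and the Y-linked reads were 9.84 times lower in the same libraries. Bmp4, a signalling ligand of the mesoderm list, rose from 1.91 ± 0.0413 to 26.7 ± 0.615 FPKM. In that list of 8 measured genes, 5 were higher and 2 lower (camera adjusted p = 0.230), with Evx1 at 1.14, the Brachyury gene T at 1.11 and Gsc at -1.10. Of 6 neural ectoderm genes, 4 were lower, 1 higher and 1 did not pass (adjusted p = 0.288), with Nes at -1.11 and Gbx2, also a naive pluripotency gene, at 1.95. Of 17 trophoblast genes, 9 were higher and 3 lower (adjusted p = 0.137, but 0.0400 among genes of mean FPKM at least 5), with Rhox6 at 0.96, Tead4 at 0.86 and Krt18 at 0.85.

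Genes of the 2-cell-like state were higher in p53-deficient cells, where 7 of 7 measured genes rose (median log2 fold change 0.84, camera adjusted p = 0.0207, and adjusted p = 0.195 with an estimated correlation). Zscan4d went from 0.388 ± 0.0720 to 1.57 ± 0.214 FPKM and Usp17lb from 0.384 ± 0.175 to 1.66 ± 0.227 FPKM. Zscan4d, Gm8300 and Eif1a each have an expressed near-identical copy, and without genes that have a copy the list had too few genes to test. Apart from Eif1a, at 93.6 and 99.1 FPKM, all were low, and Eif1a, with 0.08, did not pass under either scaling alternative or without a variance trend. Of 26 germ cell genes, 16 were higher and 7 lower (adjusted p = 0.175, but 0.00562 without a filter on low values). Taf7l and Mov10l1 rose from 6.75 ± 0.446 to 30.7 ± 1.35 FPKM and from 1.43 ± 0.0521 to 8.85 ± 0.131 FPKM, and Stra8, a gene of meiotic entry, fell from 12.8 ± 0.188 to 1.46 ± 0.344 FPKM. Among maternally expressed imprinted genes 10 of 21 were lower and 8 higher (adjusted p = 0.322), or 10 and 5 after scaling by the median log2 ratio. H19 fell from 64.4 ± 0.102 to 10.2 ± 0.634 FPKM, while Rian and Mirg rose with 1.31 and 1.34. Dcn, which fell with -2.24, is also in the fibroblast list, and the Y-linked reads were 9.84 times lower in the same libraries. Among 21 paternally expressed genes 9 were higher and 8 lower (adjusted p = 0.944), or 8 and 10 after scaling by the median log2 ratio, with Nnat at 1.29, Mest at 1.12 and Plagl1 at -1.67. Exons of Mest overlap Copg2 over 23.1% of their length.

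Genes of the cell cycle changed by small amounts, apart from a few regulators of entry into S phase. Among 38 G1 to S genes, 19 were higher and 11 lower (camera adjusted p = 0.397). Cdc6, a replication licensing factor, rose from 13.5 ± 0.106 to 33.1 ± 0.692 FPKM and Myc rose with 1.22. The inhibitor Cdkn2b fell from 16.6 ± 0.448 to 3.73 ± 0.311 FPKM, Ccnd2 from 12.7 ± 0.241 to 2.94 ± 0.242 FPKM, and the retinoblastoma gene Rb1 from 3.56 ± 0.146 to 0.360 ± 0.0389 FPKM. Y-linked reads were 9.84 times lower in the same libraries. Whether Cdkn2b, Ccnd2 and Rb1 fell in the stem cells themselves was not tested. Of 43 mitosis and cytokinesis genes, 21 were higher and 12 lower (adjusted p = 0.294), none by 2-fold. Espl1 (separase) rose with 0.53, Ndc80 with 0.50 and Cdc25c with 0.46, Cenpe fell with -0.43, and Top2a was 73.4 ± 0.668 against 71.1 ± 1.4 FPKM. Of 42 DNA repair genes, 19 were higher and 14 lower (adjusted p = 0.944), none by 2-fold, with Blm at 0.64, H2afx at -0.66 and Xrcc1 at -0.80. After scaling by the median log2 ratio these counts became 15 higher and 17 lower for G1 to S, 15 and 15 for mitosis, and 10 and 21 for DNA repair. In the list of p53 family genes and regulators, 8 of 21 were higher and 9 lower (adjusted p = 0.831). Trp73 fell from 2.35 ± 0.143 to 0.165 ± 0.0167 FPKM and Mdm4 from 15.9 ± 0.147 to 5.34 ± 0.271 FPKM, and Wrap53, the antisense neighbour of Trp53, was 15.5 ± 0.675 against 15.8 ± 0.830 FPKM.

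Stress genes fell and sterol genes rose. Of 27 genes of the unfolded protein and amino acid stress responses, 24 were lower, none was higher and 3 did not pass (median log2 fold change -0.73, camera adjusted p = 1.15e-08, and adjusted p = 0.0891 with an estimated correlation). Ddit4 fell from 84.4 ± 2.39 to 6.61 ± 0.75 FPKM, Nupr1 from 31.9 ± 1.09 to 1.92 ± 0.199 FPKM, and Sesn2, also a p53 target, from 56.5 ± 1.57 to 10.4 ± 0.761 FPKM. The chaperone gene Hspa5 was 191 ± 0.736 against 187 ± 1.88 FPKM and did not pass. The Y-linked reads were 9.84 times lower in the same libraries. Of 24 cholesterol synthesis genes, 22 were higher and 2 did not pass, with 1 lower under each scaling alternative (median log2 fold change 0.43, camera adjusted p = 3.01e-06, and adjusted p = 0.0891 with an estimated correlation). Stard4 rose from 4.04 ± 0.337 to 12.7 ± 0.672 FPKM, Sqle from 16.4 ± 0.546 to 42.6 ± 0.582 FPKM and Pmvk from 17.6 ± 0.541 to 38 ± 0.359 FPKM. Acat2, at 38.9 ± 0.155 and 37.0 ± 2.12 FPKM, did not pass.

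Adjusted over the list alone, the counts of the other fixed lists differed from those over all genes in 6 lists. They were 11 lower for the death receptor list, 15 lower for DNA repair, 12 lower for G1 to S, 10 higher for primed and formative genes, 2 higher for neural ectoderm and 9 higher for p53 family genes.

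Other metabolic and signalling lists were not called. Of 24 glycolysis genes, 14 were lower and 8 higher (adjusted p = 0.154, but 0.0422 among genes of mean FPKM at least 5 and 0.0470 with voom weights), or 14 and 5 after scaling by the median log2 ratio, with Eno2 at -1.98 and Slc16a3 at -1.65. Gapdh, which has many near-identical copies, ranged from 8.04 to 65.3 FPKM among the WT libraries alone. Of 35 nuclear oxidative phosphorylation genes, 18 were higher and 2 lower (adjusted p = 0.0966, but 0.0318 without p53-deficient replicate 3 and 0.00493 without a filter on low values), a split that became 10 and 10 after scaling by the median log2 ratio. Of 13 mitochondrially encoded genes, 6 were lower and none higher (adjusted p = 0.285), with 3 higher after quantile normalization and mt-Nd5 at -0.67. Of 29 Wnt genes, 13 were higher and 13 lower (adjusted p = 0.903), or 12 and 15 after scaling by the median log2 ratio. Wnt7b rose with 1.51 and Sp5 with 1.27, while Wnt5a fell with -1.90 and Fzd1 with -1.57. Of 27 interferon response genes, 15 were higher and 11 lower (adjusted p = 0.705). Oas2 rose with 2.47, whereas Ifit1 fell from 12.1 ± 0.527 to 1.4 ± 0.0811 FPKM and B2m, the light chain of class I antigen-presenting molecules, from 216 ± 4.67 to 45.4 ± 0.477 FPKM. In the same libraries the Y-linked reads were 9.84 times lower. Whether Eno2, Slc16a3, Wnt5a, Fzd1, Ifit1 and B2m fell in the stem cells themselves was not tested.

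**Figure D3:**
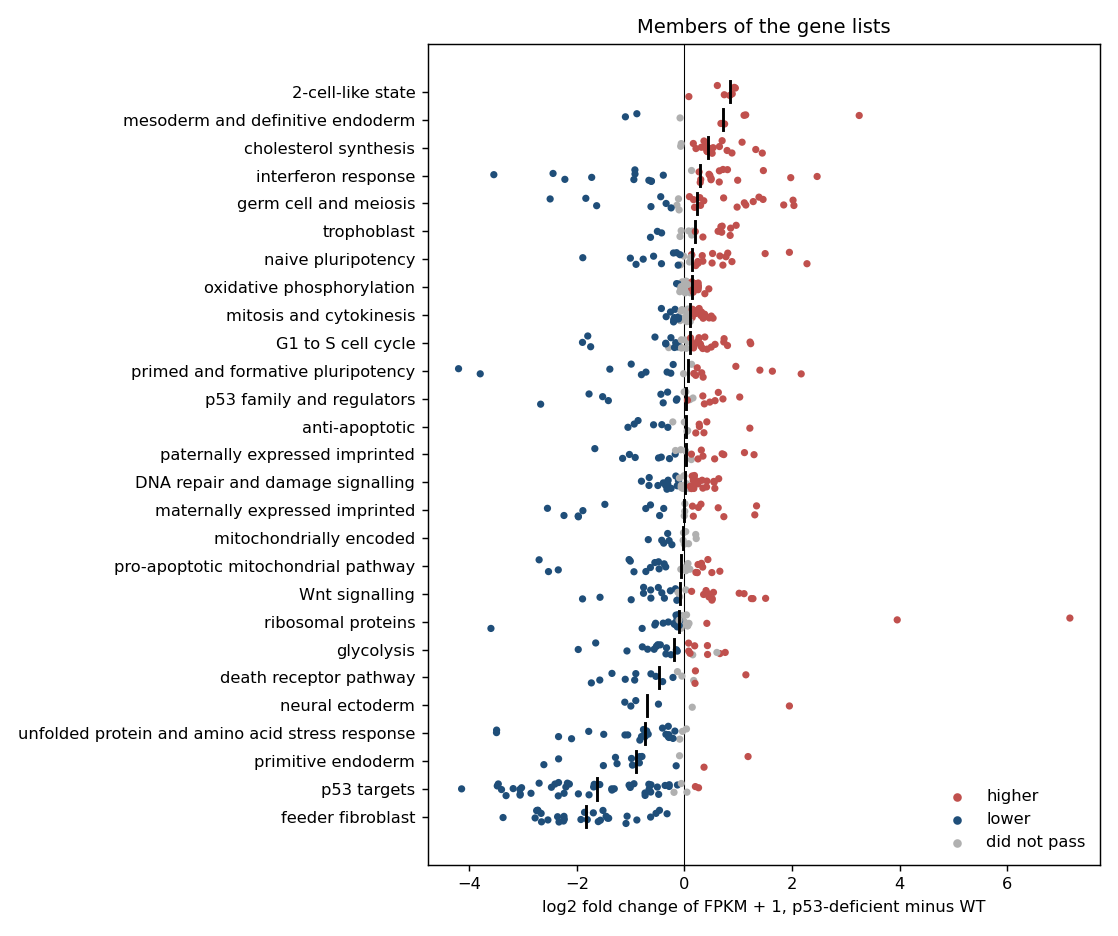
Log2 fold change (p53-deficient minus WT, on the FPKM + 1 scale) of each measured member of the 27 gene lists, coloured by whether it was higher, lower or did not pass at an adjusted p of 0.05, with the list median as a black bar. Medians run from -1.83 in the feeder fibroblast list to 0.84 in the 2-cell-like list.

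The largest falls among named protein-coding genes, on the log2(FPKM + 1) scale, were in Nr1h5, a nuclear receptor gene, from 65.4 ± 1.02 to 0.0168 ± 0.0155 FPKM, and in Baiap2l1, from 69.0 ± 0.586 to 1.23 ± 0.135 FPKM. Lefty1, Eda2r, Ptx3, Ipp, Cxcl5, Lefty2, Cxcl1, Rpl30, Ifit3 and Nupr1 completed the 12. The chemokine genes Cxcl5 and Cxcl1 fell with -3.90 and -3.63 and Ptx3 with -4.14, in the libraries in which the Y-linked reads were 9.84 times lower. Their WT over p53-deficient read ratios were 22.4 (95% interval 19.3 to 26.2), 19.1 (16.4 to 22.4) and 29.55 (25.5 to 34.4). These intervals, of counting error only, lay above the upper limit of the pooled Y-linked ratio, 12.2. The genes were picked as the largest falls. Among named protein-coding genes outside the ribosomal proteins, the largest rises on that scale were in Ifi27, an interferon-induced gene, from 7.45 ± 0.414 to 122 ± 5.53 FPKM, and Nefm, a neurofilament gene, from 0.696 ± 0.0537 to 22.2 ± 0.470 FPKM. Oasl1, Slc13a5, Gsdmc4, Bmp4, Spry4 and Snai3 rose with log2 fold changes between 3.14 and 3.34. The expressed neighbour Nefl overlaps 19.2% of the exon length of Nefm.

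Ribosomal protein genes and processed pseudogenes were among the genes with the most extreme values, and these values are uncertain where the genes have near-identical copies. Rps2 went from 6.83 ± 2.35 to 1092 ± 43.1 FPKM, while its pseudogene Rps2-ps13 went from 2594 ± 17.1 to 208 ± 14.9 FPKM. Another of its pseudogenes, Rps2-ps6, rose with it, from 0.705 ± 0.512 to 32.0 ± 7.85 FPKM. Rps18 went from 29.4 ± 1.24 to 471 ± 17.9 FPKM while its copy Gm11361 went from 469 ± 20.9 to 18.8 ± 3.16 FPKM. Rpl26 and Gm15772, and Rpl30 and Gm12191, made similar opposite moves. Over the ribosomal protein list, 20 of 39 members were lower, 3 higher and 16 did not pass, or 32, 2 and 5 after scaling by the median log2 ratio, with a median log2 fold change of -0.10 and a mean of 0.08. Its camera adjusted p of 0.0399 became adjusted p = 0.707 with an estimated correlation, and the call also ended with quantile normalization, with protein-coding genes only and without WT replicate 1 or 2 or p53-deficient replicate 2 or 3, where adjusted p lay between 0.0667 and 0.110. Without genes that have a copy adjusted p was 0.468. Actg1, the most abundant actin gene among those changed 2-fold, rose from 575 ± 1.33 to 1215 ± 42.3 FPKM and also has copies.

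**Figure D4:**
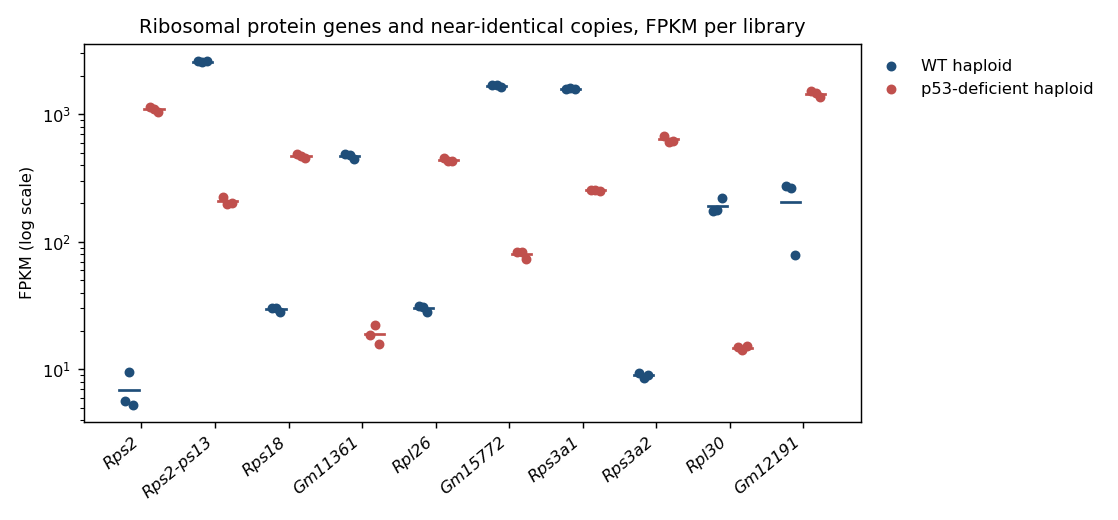
FPKM of ribosomal protein genes beside near-identical copies in each library (points, log scale), with group means as lines. Rps2 rises from 6.83 to 1092 FPKM where Rps2-ps13 falls from 2594 to 208 FPKM, and in each other pair the members move in opposite directions, Rpl30 and Rps3a1 falling where their copies rise.

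No chromosome had a median change near 2-fold. The median log2 fold change per chromosome ran from -0.04 to 0.09 over 20 chromosomes. Single genes planted with 2-fold changes fitted a median absolute value of 0.85 in simulated data. A gain of a whole chromosome was not simulated, so a smaller gain, or one in part of the cells, stays open. No chromosome was called by camera (smallest adjusted p = 0.929, and 0 at an unadjusted p under 0.05). With an estimated correlation the smallest adjusted p was 0.223, with 2 at an unadjusted p under 0.05.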

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

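Removal of genes with a near-identical copy was chosen after seeing the data, and all other alternatives were planned. The counts of changed, higher and lower genes and of genes changed at least 2-fold stayed within 1.5 times in 67 of 72 values. The exceptions were 5944 changed, 2268 lower and 661 at least 2-fold among genes of mean FPKM at least 5, where fewer genes were tested, and 2603 at least 2-fold with a pseudocount of 0.1 and 2780 with voom, for which the cause was not tested. With the replicate block 9766 genes were called, 9516 of them also called without it. The replicate number did not pair libraries: deviations of like-numbered libraries correlated across genes at -0.0328, 0.0142 and 0.00556. Leaving out each library gave 9268 to 9721 changed genes. The p53 target list kept its call under every alternative except the estimated correlation, where adjusted p = 0.0891 with 1.16e-22 to 3.33e-13 under the others. Of 483 list values, this one included, 20 lost and 7 gained a call. Without near-copy genes, and also among genes of mean FPKM at least 5, the 2-cell-like list had too few genes to test. Of 3190 values of named genes, 43 passed only under the alternative and 5 no longer passed. The cause was not tested for the reversals that follow, none of which concerned a called list or chromosome. Depth limits weak genes most, since the shallowest library held 11536412 reads.

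Lists that turned direction did so at these adjusted p. Among genes of mean FPKM at least 5 they were anti-apoptotic and DNA repair (both 0.773), paternally expressed (0.725) and Wnt (0.940). Without a filter it was mesoderm (0.817). With median-ratio scaling they were DNA repair (0.866), primed and formative (0.9985), paternally expressed (0.929) and Wnt (0.964). With quantile normalization they were DNA repair (0.849) and paternally expressed (0.949). DNA repair turned with the replicate block (0.986), paternally expressed with protein-coding genes (0.884) and voom (0.878), and Wnt with voom (0.994). Without near-copy genes p53 family (0.554) and Wnt (0.988) turned. Paternally expressed genes ranged from 0.925 to 0.995 over the libraries left out.

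Chromosomes 7, 8 and 13 turned at mean FPKM at least 5 (0.854 each), 17 without a filter (0.990), and 13 with protein-coding genes (0.987) and without near-copy genes (0.968). Quantile normalization turned 4 (0.9805), 6 (0.955) and 13 (0.955). Chromosome 6 ranged from 0.936 to 0.981 over the libraries left out.

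Genes that turned had these log2 fold changes. With median-ratio scaling they were Bak1 -0.03409, Cdk4 -0.08775, Ctnnb1 -0.07439, mt-Nd1 -0.02344, Rpl8 -0.03782, Wrap53 -0.07483, Xiap -0.04014 and Eif1a -0.01743. With quantile normalization they were Apoa1 0.0003284, Bak1 -0.0383, Cdk4 -0.05636, Ctnnb1 -0.07203, H13 0.05257, Tex14 0.006651 and Wrap53 -0.03614, and with voom H13 0.0006156. Over the libraries left out the ranges were -0.009962 to 0.06607 for Wrap53, -0.03775 to 0.05239 for H13, -0.3877 to 0.2758 for Apoa1, -0.01888 to 0.03163 for Cdk4, -0.1045 to 0.4961 for Fthl17-ps1, -0.03895 to 0.008198 for Etv5 and -0.07606 to 1.552 for Gapdh. Of these genes only Eif1a was called.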

Other observations

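The gene groups of the next paragraph and the tests of Y-linked reads, p53 target ratios, near-identical copies, copy families and the ribosomal class were chosen after the results were seen, while thinning to equal depth and the splits of the libraries were planned.

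Genes induced by FGF and ERK signalling were mostly higher in p53-deficient cells. Of 19 genes, 13 were higher, 4 lower and 2 did not pass (median log2 fold change 0.63, camera adjusted p = 0.00588, and adjusted p = 0.0626 with an estimated correlation). Spry4, a feedback inhibitor of the pathway, rose from 1.43 ± 0.191 to 20.9 ± 0.417 FPKM, Fos with 2.26 and Egr1 with 2.16, while Ier3 fell with -2.44. Targets of Nodal and TGF-beta signalling were mostly lower, 8 of 11 with 2 higher (median -0.87, adjusted p = 0.00588, and adjusted p = 0.0626 with an estimated correlation). Nodal fell from 34.5 to 19.4 FPKM, while Tgif1 and Smad7 were higher. Of 9 BMP targets 4 were higher and 4 lower (adjusted p = 0.650), with Id1 at 2.16, Id3 at 1.08 and Id2 at -0.59 beside the rise of Bmp4. Of 22 chemokine and matrix remodelling genes 19 were lower and 2 higher (median -1.38, adjusted p = 1.22e-07, and adjusted p = 0.0147 with an estimated correlation), Ccl2 falling from 125 to 14 FPKM and Ccl7 from 103 to 12 FPKM. The Y-linked reads were 9.84 times lower in these libraries, and several of the chemokines are also made by fibroblasts. All gene groups of this paragraph were chosen after the results were seen, so their camera p-values cannot test them and carry no weight. These p-values were adjusted over the groups of this paragraph alone, apart from the fixed lists. The camera adjusted p of 0.0147 therefore does not set the chemokine group above the fixed lists.

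The fall of all 30 fibroblast genes may come from less RNA of feeder cells, which the labels do not mention. The pooled Y-linked reads, absent from cells without a Y chromosome, were 9.836 times lower in p53-deficient libraries, and the 30 genes had a median ratio of 4.63, a highest of 12.7 and a lowest of 1.249, with Timp1, Vim, Cyr61 and S100a6 at the low end. With every library thinned to the shallowest, the list's median log2 fold change was -1.88. FPKM is already scaled to library size, so thinning had little room to move this median and is no strong test of depth. Whether the stem cells carry a Y chromosome is not given in the sources used here. The 660 X-linked genes tested had a median log2 fold change of 0.09, so X-linked RNA did not fall with the Y-linked reads. This median does not tell lost feeder RNA from a lost Y chromosome. Haploid cells whose single chromosome set holds an X would carry no Y, and a doubling of that set would add none. Neither the chromosomes of the lines nor their ploidy were measured. Of the fibroblast genes, 2 stand in another fixed list. A change of these genes in the stem cells themselves stays open and was not tested.

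The fall of p53 targets may itself come in part from lost feeder RNA, since feeder cells with intact p53 would also express them. Of 48 targets, 2 had a ratio whose lower 95% limit lay above the Y-linked upper limit of 12.2, Eda2r at 62.6 (51.9 to 76.2) and Psrc1 at 14.3 (13.1 to 15.7), while Gdf15, Dcxr, Trp53inp1 and Phlda3 lay above 12.2 with lower limits under it. The bounds on this count were set after the ratios were seen and 2 genes are too few, so the count leaves feeder RNA as the whole cause open, although the lower limit of Eda2r lies far above 12.2. Of the other 46 targets 5 were not lower, and for the 41 that were it cannot be told apart from loss of p53 in the stem cells, because no profile of the feeder cells is at hand. Trp53 itself had a ratio of 6.95 (6.63 to 7.29).

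Opposite moves of ribosomal protein genes and their pseudogenes may reflect reads placed on different members of a family. Among 73 called genes of absolute log2 fold change at least 3, 41.1% had a near-identical copy against 16.3% of genes of like expression, a ratio of 2.522 that lay between the bounds set. Of the 25 processed pseudogenes and ribosomal protein genes among them 24 had a copy (96%), against 89.9% of others of that class of like expression, which leaves sharing of reads open. The summed reads of 14 families, the largest of 357 genes, had a median absolute log2 ratio of 0.2389, but this decides nothing, since a change of the extreme members alone would have moved only 2 of the 14 sums by 2-fold or more, and both sums did move by more than 2-fold. A change of 2-fold or more in ribosomal protein transcripts as a class is argued against by their median of -0.1006. Of 39 members, 36 lay within 1 of 0 on the log2 scale. A small fall of the class stays open, since 20 were lower and 3 higher. Sequence differences between the lines and true differences between copies were not tested.

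The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 10074 genes, 5341 higher, 4733 lower and 1472 at least 2-fold, the highest of the other splits called 0 of each (limma, 110 to 160 genes at an unadjusted p under 0.05, against 10543), and 1 split, the real one, reached each of these counts. The p53 target list's median lay 1.63 from 0 in the real split and at most 0.558 from 0 in the others. Each other split mixes the groups on both sides, which shrinks a group difference and adds it to the spread within each side. Lower values there follow from the group difference itself, so their distance from the real split does not measure chance.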
